A study of Oryza sativa with 18 samples.

How the data were processed

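The 18 MethylC-seq libraries came from rice embryos (dry seed, 24 h in air, 24 h in nitrogen) and coleoptiles (4 d in air, 4 d in nitrogen, 3 d in nitrogen then 1 d in air), with 3 libraries per group. Per the labels' protocols, each library was made from 600 ng of genomic DNA with 0.5% of lambda DNA added, and primary leaf tissue was removed from air-grown coleoptiles. Each library was assigned to its group by its title, and each column of the tables to its library by the group and replicate number in the column name, with 0 columns of per-library values left unused.

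The authors deposited 3 tables of differentially methylated regions. Per the file headers, each region has a chromosome, a start, an end and a set of columns per library. The deposited total read count per region and library is a whole number. The column names do not say whether reads were counted per molecule or per cytosine. The deposited methylated read values were treated as estimated counts, because each is a whole number times a factor of the library between 0.9977 and 0.9983, and 100% of the values came out whole to within 0.01 after division. What the factor corrects for is not given in the sources used here. The deposited percent equals the methylated value over the total count, and it is written as 0 where the total is 0, so those entries were treated as missing. The column names carry the context CG, but the deposited names of all 3 sets of regions carry CNN. The sources used here do not explain this, so the context of the counted cytosines is not settled. The aligner, the caller of regions, its filters and the genome build are not given in the sources used here. The table for the dry seed gives also the number of differentially methylated sites, between 3 and 90 per region, and, by name, the libraries the authors listed as high or low. A pair of further numeric columns held only the length of those lists as text in all 5908 rows and was not used.

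Total reads over the regions were between 865237 and 2150760 per library in the dry seed table, between 396689 and 531162 in the oxygen table and between 119663 and 219640 in the re-aeration table. The total is over the regions of a table and not the depth of a library. At most 75 regions per library in the dry seed table, 3 in the oxygen table and 18 in the re-aeration table had fewer than 10 reads. Reads over neighbouring cytosines of a molecule are not independent, so the model estimated the spread from the libraries. No pair of libraries agreed within the noise that independent reads would give, which dependence between reads can cause by itself. The mean chi-square with 1 degree of freedom per region between libraries of a group was between 2.49 and 11.2. It was 9.90 to 11.0 in the dry seed and 8.69 to 9.05 after re-aeration in the dry seed table, and 10.5 to 11.2 after re-aeration in the re-aeration table. It was at most 4.60 in all other groups and in the oxygen table.

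A region was tested with a quasi-binomial logistic model on the methylated counts, rounded to whole numbers, and the total counts. The model had a term per group and no covariate, and all groups of a table shared the spread of a region, with the dispersion kept at 1 or above. Libraries with fewer than 10 reads in a region were left out there, and a comparison needed 2 libraries per group. A region was called at a Benjamini-Hochberg adjusted p under 0.05 over the regions of its table with a difference of group means of at least 10 points. The 5 comparisons between the groups of each table were fixed before the data were examined. The other 8 comparisons, between groups quantified in a table made for another comparison, were added after seeing the data. The plan named limma for tables of levels and the quasi-binomial model where read counts were given. Mean levels per library were compared by exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3. Overlaps were taken with bedtools at 1 bp or more and set beside 1000 random placements of the same lengths on the same chromosomes, which ignore where regions could be called. Shared control libraries were handled by 100 simulations of unchanged groups.

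The model was tested on simulated counts at the real depths before use, with the median dispersion of the table given to every region and group. In each comparison 100 regions were shifted by 20 points and 100 by 30 points. The simulation did not hold the wider spread of the dry seed and re-aeration libraries, so its few false calls do not cover it. In the dry seed table it recovered 29 and 61 for 24 h air, 26 and 73 for 24 h nitrogen, and 28 and 50 for nitrogen against air at 24 h, and called 2, 3 and 2 of the 5708 unshifted regions. For 4 d nitrogen against air it recovered 32 and 62 and called 2 of 1931. For re-aeration against nitrogen it recovered 28 and 52 and called 1 of 702. A difference of 20 points was therefore often missed in these simulations. Few regions were shifted in them, which makes the Benjamini-Hochberg adjustment stricter than where most regions of a table differ. The recovery therefore does not give the power of the real comparisons in which most regions were called.

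The regions named in the text follow a rule fixed before the data were examined. With no annotation of the build, these are the 5 largest differences per comparison and direction among called regions whose libraries do not overlap between the groups, with at least 4 differentially methylated sites where the number is given. Regions outside the rule are named as chosen after their values were seen. Without the build, the planned comparison of regions with gene positions and the 10 gene lists fixed before the data were not analysed here.

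The alternatives tried were a minimum difference of 20 points or none, only regions with at least 8 sites, limma on the arcsine square root or on the log2 ratio of methylated to unmethylated level with 0.01 added, only regions complete in all libraries, the replicate number as a block, the spread of the compared groups alone, a minimum of 20 reads, and each library left out in turn. Mean levels were also taken as medians and weighted by length, and overlaps with at least 50% of each region shared. Chosen after seeing the data were limma on the levels, no lower bound on the dispersion, the spread without the dry seed and re-aeration libraries, and regions with a read ratio within 0.25 on the log2 scale of that in the oxygen table. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with limma 3.58.1.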

Results

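DNA methylation was measured in rice (Oryza sativa cultivar Amaroo) by MethylC-seq, a bisulfite sequencing method that reads whether each cytosine carries a methyl group. The 18 libraries formed 6 groups of 3: embryos of the dry seed at 0 h, embryos after 24 h in medium bubbled with air, embryos after 24 h in medium bubbled with nitrogen gas, coleoptiles after 4 d in air, coleoptiles after 4 d in nitrogen, and coleoptiles after 3 d in nitrogen followed by 1 d in air (called re-aeration here). The coleoptile is the sheath around the first leaf, and it is the organ by which rice elongates without oxygen. Seedlings were grown in the dark at 30 °C.

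The values came from 3 tables of regions that the authors had picked because methylation differed between groups. The dry seed table held 5908 regions for the dry seed against both 24 h groups, the oxygen table held 2131 regions for 4 d air against 4 d nitrogen, and the re-aeration table held 902 regions for 4 d nitrogen against re-aeration. The regions were short, with a median length of 58 bp in the dry seed table, 37 bp in the oxygen table and 47 bp in the re-aeration table. The dry seed table covered all 18 libraries and the other tables the 9 coleoptile libraries. The median number of reads per region and library lay between 114 and 287 in the dry seed table, between 141 and 189 in the oxygen table and between 98 and 178 in the re-aeration table. A methylation level is the percent of these reads that were methylated, and all differences are in percentage points. If reads were counted per cytosine, which the column names leave open, the read numbers here and below exceed the number of molecules. The labels do not say that the libraries of a group came from separately grown cultures, so p-values measure only the spread between these libraries, which may be technical. Because the regions were picked for a difference, the counts below describe the regions and are not independent evidence that a difference exists. The genome build is not given in the sources used here, so positions are those of the authors' tables and no gene was assigned to a region.

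**Figure D1:**
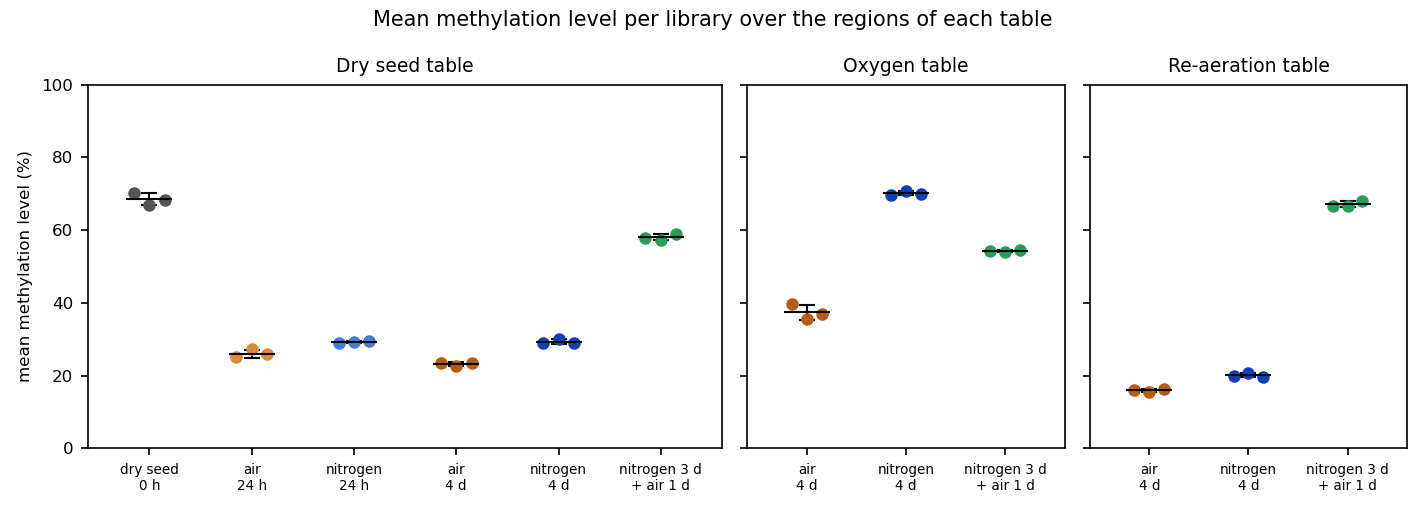
Mean methylation level in percent of each library (points) over all regions of the dry seed table, the oxygen table and the re-aeration table, with the group mean (dash) and SD (bars, n = 3). The dry seed and re-aeration groups stand at 68.4% and 58.1% in the dry seed table, and the re-aeration group at 54.3% lies between 4 d air and 4 d nitrogen in the oxygen table.

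The first question was how methylation changed when the dry embryo germinated in air. Methylation was lower after 24 h in air in nearly all regions of the dry seed table. The mean level over the regions was 68.4% ± 1.66 (SD, n = 3) in the dry seed and 26.04% ± 1.11 (SD, n = 3) after 24 h in air. The median region fell by 41.3 points, with an interquartile range of -52.6 to -31.2. On chromosome 11, the region from 24548583 to 24548626 went from 98.4% ± 2.48 (SD, n = 3; 58 to 187 reads) to 0.421% ± 0.729 (SD, n = 3; 14 to 79 reads), a difference of -97.9 points. On chromosome 11, the region from 8670062 to 8670078 went from 94.3% ± 6.02 (SD, n = 3; 96 to 156 reads) to 0% in each of the 3 air libraries, which had 10 to 32 reads. On chromosome 7, the region from 24599436 to 24599451 went from 95.7% ± 3.56 (SD, n = 3; 143 to 164 reads) to 1.85% ± 3.20 (SD, n = 3; 10 to 36 reads). The next in size was the region on chromosome 5 from 18241761 to 18241774, with a difference of -93.6 points (n = 2 in air, 9 to 36 reads). The region on chromosome 6 from 14291732 to 14291742 followed with -90.7 points (n = 3 in air, 10 to 16 reads). Read ranges include libraries left out for fewer than 10 reads.

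The quasi-binomial model called 5844 of 5900 tested regions lower and 1 higher after 24 h in air. The 1 higher region, on chromosome 9 from 22628729 to 22628745, was chosen after its values were seen. It stood at 17.9% ± 12.5 (SD, n = 3; 35 to 66 reads) in the dry seed and 46.9% ± 25.5 (SD, n = 3; 60 to 90 reads) in air, and its adjusted p in the quasi-binomial model was 0.0346. This call was lost with the replicate block, with the spread of the compared groups alone, and without dry seed library 1 or 3 or air library 2. The 3 libraries of each group did not overlap in 97.3% of the regions. Chance would give 10% in regions not picked for a difference between these libraries, but these regions were so picked. The exact two-sided permutation test on the 3 library means per group gave p = 0.1, the smallest value that 3 against 3 allows. The dry seed libraries also stood apart in these regions in their reads, with a median log2 read ratio of 0.82 over 24 h air, and in the spread between libraries, with a mean chi-square per region of at least 9.90 for each pair against at most 3.72 in 24 h air. The chi-square rises with the number of reads. The median absolute difference between libraries was 7.34 to 7.84 points in the dry seed and 5.15 to 5.32 in 24 h air.

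The second question was whether methylation was also lower after 24 h without oxygen. After 24 h in nitrogen the mean level was 29.2% ± 0.199 (SD, n = 3), and the median region fell by 38.1 points from the dry seed. The region on chromosome 11 from 24548583 to 24548626 again had the largest difference, at -95.4 points, with 3.01% ± 2.63 (SD, n = 3; 24 to 82 reads) in nitrogen. On chromosome 6, the region from 6665185 to 6665216 went from 93.5% ± 3.02 (SD, n = 3; 321 to 334 reads) to 2.44% ± 2.14 (SD, n = 3; 19 to 30 reads). The region on chromosome 11 from 8670062 to 8670078 differed by -94.3 points (n = 2 in nitrogen, 6 to 20 reads). The region on chromosome 4 from 18045597 to 18045627 differed by -92.2 points (n = 2 in nitrogen, 0 to 49 reads). The region on chromosome 11 from 24483883 to 24483912 differed by -91.1 points (n = 3 in nitrogen, 16 to 80 reads).

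The model called 5707 of 5892 tested regions lower in nitrogen than in the dry seed and 0 higher, with 5770 regions at an unadjusted p under 0.05. Of the regions of the table, 5681 were called lower in both gases, 163 in air and not in nitrogen, and 26 in nitrogen and not in air. In the authors' deposited table, 5426 of the 5908 regions listed both a 24 h air library and a 24 h nitrogen library as low. The changes in air and in nitrogen had the same sign in 99.9% of regions, and their Pearson r across regions, which are not independent replicates, was 0.918. Both changes share the dry seed libraries. Unchanged groups simulated against those libraries gave the same sign in 71.7% of regions and an r of 0.621. The covariance was 233.4, against 29.8 in the simulation, a difference of 203.6. Independent lists of these lengths would share 5645 regions. The 3 dry seed libraries were not split, because a part would hold a single library, so part of the excess over the simulation may come from the shared controls. The simulation also left out the picking of regions by the authors, which favours a fall in both gases and so the same sign. The excess over the simulation is therefore not evidence that the changes agree.

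The third question was whether oxygen changed the outcome at 24 h. The regions of the dry seed table stood a little higher in nitrogen than in air, with a mean level of 29.2% ± 0.199 (SD, n = 3) against 26.04% ± 1.11 (SD, n = 3) and a median difference of 2.62 points. The difference was above 0 in 4131 regions and below 0 in 1734. A single region passed the test. On chromosome 8, the region from 24216619 to 24216654 kept 95.8% ± 0.288 (SD, n = 3; 190 to 243 reads) in nitrogen and stood at 71.5% ± 4.24 (SD, n = 3; 132 to 273 reads) in air, against 97.1% ± 1.05 (SD, n = 3; 276 to 384 reads) in the dry seed.

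Of 5886 tested regions, 1 was called higher in nitrogen and 0 lower in the quasi-binomial model. There were 377 regions at an unadjusted p under 0.05, and limma on the levels called 5 higher and 0 lower. The libraries did not overlap in 15.7% of regions, against 10% by chance, and the exact two-sided permutation p of the library means was 0.1, the smallest possible. The call of the chromosome 8 region was lost with the spread taken from the compared groups alone, where its adjusted p in the quasi-binomial model was 0.706, and over all alternatives the adjusted p was between 0.00755 and 0.706. It was lost also when air library 1 or 3, or nitrogen library 1, 2 or 3, was left out, which gave 0 called regions each time.

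**Figure D2:**
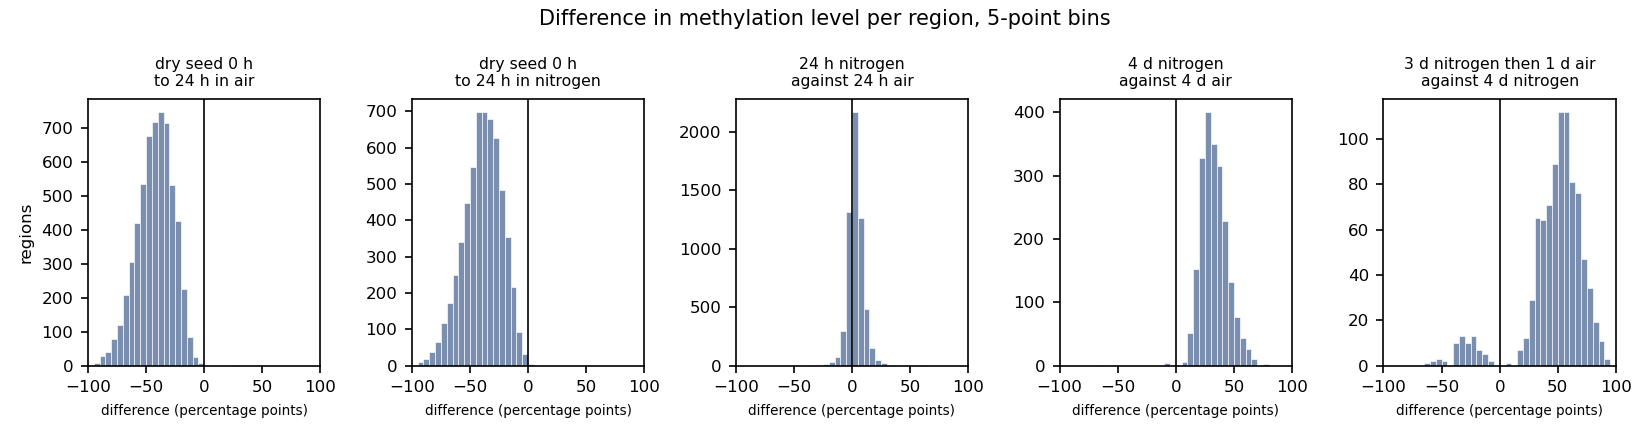
Number of tested regions (y axis) by difference in methylation level in percentage points (x axis, bins of 5 points) for the 5 comparisons fixed before the data were examined, second-named minus first-named group for the dry seed and first-named minus second-named for the others. The medians are -41.3 and -38.1 points for the dry seed to air and to nitrogen, 2.62 for 24 h nitrogen against air, 31.6 for 4 d nitrogen against air and 52.0 for re-aeration against 4 d nitrogen.

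The fourth question was how coleoptiles grown without oxygen differed from those grown in air. Primary leaf tissue was removed from the air-grown coleoptiles, so these groups may also differ in dissection and in the tissue sampled. Such differences cannot be told apart from those of oxygen here. Methylation was higher in nitrogen in nearly all regions of the oxygen table. The mean level was 37.3% ± 2.00 (SD, n = 3) in 4 d air and 70.1% ± 0.475 (SD, n = 3) in 4 d nitrogen, and the median difference was 31.6 points with an interquartile range of 24.9 to 39.7. On chromosome 6, the region from 28477079 to 28477083 stood at 6.47% ± 5.64 (SD, n = 3; 22 to 29 reads) in air and 85.5% ± 10.1 (SD, n = 3; 19 to 37 reads) in nitrogen. The region on chromosome 3 from 12515856 to 12515867 stood at 14.5% ± 2.70 (SD, n = 3; 56 to 70 reads) in air and 83.1% ± 1.36 (SD, n = 3; 42 to 83 reads) in nitrogen. The others of the largest were on chromosome 1 from 42160349 to 42160351, with a difference of 77.2 points, on chromosome 3 from 20180142 to 20180148, with 69.0 points, and on chromosome 7 from 26126515 to 26126521, with 68.1 points.

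Only 2 regions were called lower in nitrogen. On chromosome 2, the region from 10863433 to 10863442 stood at 90.9% ± 2.94 (SD, n = 3; 37 to 49 reads) in air and 23.6% ± 6.20 (SD, n = 3; 35 to 49 reads) in nitrogen. The region on chromosome 11 from 1949445 to 1949490 stood at 45.9% ± 8.07 (SD, n = 3; 122 to 173 reads) in air and 17.2% ± 3.86 (SD, n = 3; 137 to 182 reads) in nitrogen. The model called 2101 of 2131 regions higher in nitrogen. The libraries did not overlap in 97.9% of these picked regions, where chance would give 10% without picking. The exact two-sided permutation p of the library means was 0.1, the smallest possible.

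In the same regions, re-aerated coleoptiles stood between the groups kept in either gas, with a mean level of 54.3% ± 0.356 (SD, n = 3). Of the 2101 regions called higher in nitrogen, 2048 had a re-aeration level between those of nitrogen and air. The fall from nitrogen, as a percent of the gap between nitrogen and air, had a median of 49.0% and an interquartile range of 35.7% to 62.6%. On chromosome 6, the region from 28477079 to 28477083 stood at 40.2% ± 24.1 (SD, n = 3; 25 to 37 reads) after re-aeration, and the region on chromosome 3 from 12515856 to 12515867 at 58.3% ± 11.6 (SD, n = 3; 44 to 98 reads). Of the 2101 regions, 331 were called both lower than nitrogen and higher than air, 504 lower than nitrogen only, 540 higher than air only, and 726 against neither.

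Against 4 d nitrogen, the model called 835 regions lower after re-aeration and 0 higher, with 1303 regions of either sign at an unadjusted p under 0.05. Limma on the levels called 1 higher and 1155 lower. Against 4 d air the quasi-binomial model called 871 higher and 2 lower. The 2 lower were those on chromosomes 2 and 11 that were also lower in nitrogen, at 36.8% ± 6.60 (SD, n = 3) and 27.4% ± 5.12 (SD, n = 3) after re-aeration, and they were chosen here after their values were seen. The call on chromosome 11 (adjusted p = 0.0438) was lost in 5 of the 6 fits with a library left out, with the replicate block and with the spread of the compared groups alone, and that on chromosome 2 was kept in all of these. The exact two-sided permutation p was 0.1 for both comparisons of library means. The counts fell to between 197 and 324 against nitrogen and to between 373 and 647 against air when any of the compared libraries was left out.

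The fifth question was what the switch to air did in coleoptiles raised in nitrogen. The re-aeration table was made mostly of regions with higher methylation after the switch. The mean level over its regions was 15.9% ± 0.395 (SD, n = 3) in 4 d air, 20.1% ± 0.583 (SD, n = 3) in 4 d nitrogen and 67.1% ± 0.818 (SD, n = 3) after re-aeration. The region on chromosome 7 from 25616617 to 25616673 stood at 1.83% ± 2.05 (SD, n = 3; 69 to 74 reads) in nitrogen and 93.1% ± 0.757 (SD, n = 3; 255 to 286 reads) after re-aeration. On chromosome 11, the region from 25618974 to 25619077 stood at 0.197% ± 0.341 (SD, n = 3; 107 to 169 reads) in nitrogen and 89.8% ± 6.94 (SD, n = 3; 488 to 561 reads) after re-aeration. The others of the largest were on chromosome 1 from 16993953 to 16993964, with a difference of 93.2 points, on chromosome 4 from 14831420 to 14831451, with 91.1 points, and on chromosome 1 from 20069882 to 20069920, with 89.4 points.

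A smaller set of regions was lower after re-aeration. Among them, the region on chromosome 2 from 14244813 to 14244819 stood at 86.2% ± 17.4 (SD, n = 3; 12 to 39 reads) in nitrogen and 22.9% ± 16.5 (SD, n = 3; 19 to 30 reads) after re-aeration. On chromosome 2, the region from 32457519 to 32457527 stood at 69.7% ± 8.81 (SD, n = 3; 40 to 55 reads) in nitrogen, 17.9% ± 4.92 (SD, n = 3; 30 to 51 reads) after re-aeration and 30.3% ± 5.30 (SD, n = 3; 25 to 49 reads) in 4 d air. The regions on chromosome 7 from 27509115 to 27509119, on chromosome 10 from 22543607 to 22543612 and on chromosome 6 from 26626255 to 26626259 differed by -55.1, -54.8 and -51.6 points.

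The model called 818 of 901 tested regions higher and 61 lower after re-aeration. The 818 higher regions stood at 13.4% ± 0.354 (SD, n = 3) in 4 d air and 15.9% ± 0.496 (SD, n = 3) in 4 d nitrogen, and at 69.5% ± 0.757 (SD, n = 3) after re-aeration. In 536 of them both 4 d groups were under 20%. The 61 lower regions stood at 41.6% ± 1.11 (SD, n = 3) in air, 67.3% ± 1.53 (SD, n = 3) in nitrogen and 37.1% ± 1.93 (SD, n = 3) after re-aeration. Nitrogen was called above air in 2 regions of the table, chosen after their values were seen: on chromosome 11 from 3047293 to 3047326, with 49.5% ± 5.56 (SD, n = 3) in air and 85.3% ± 1.41 (SD, n = 3) in nitrogen, and on chromosome 8 from 20833712 to 20833859, with 14.7% ± 4.01 (SD, n = 3) and 44.1% ± 1.09 (SD, n = 3). Nitrogen was called below air in 0 regions, with 101 regions at an unadjusted p under 0.05, and limma on the levels called 12 higher and 0 lower. Both calls were lost when any of the air or nitrogen libraries was left out, which gave 0 each time.

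The libraries did not overlap between nitrogen and re-aeration in 96.0% of these picked regions, where chance would give 10% without picking. The exact two-sided permutation p was 0.1. The re-aeration libraries also held more reads in these regions, with medians of 153.5 to 178 against 113 to 124.5 in nitrogen, whereas in the oxygen table they held 141 to 157 against 161 to 189. Among the 112 tested regions whose read ratio lay near that of the oxygen table, an alternative added after seeing the data, 60 were called higher and 46 lower.

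**Figure D3:**
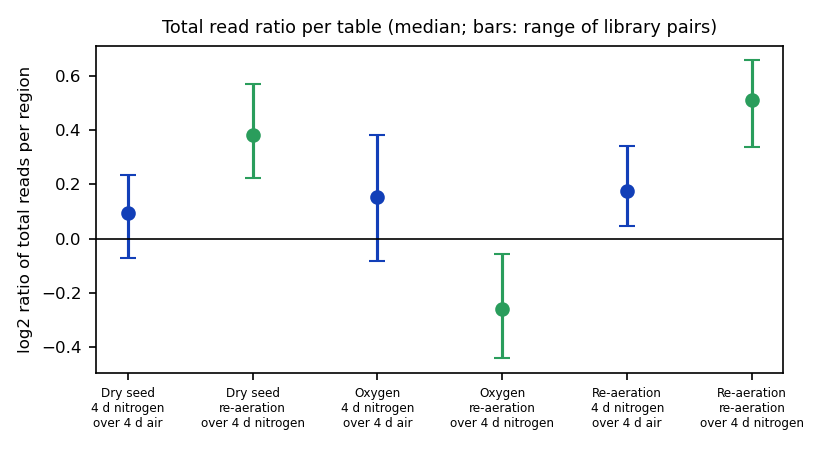
Median over regions of the log2 ratio of total reads (y axis) for 4 d nitrogen over 4 d air and for re-aeration over 4 d nitrogen in each table (x axis), with bars for the range over the pairs of libraries. Re-aeration over nitrogen is 0.51 in the re-aeration table, 0.38 in the dry seed table and -0.26 in the oxygen table.

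The regions of the dry seed table could be followed into the coleoptile, because the dry seed table also gave the 4 d libraries. They were low in both gases at 4 d and stood high after re-aeration. The mean level was 23.2% ± 0.426 (SD, n = 3) in 4 d air, 29.3% ± 0.684 (SD, n = 3) in 4 d nitrogen and 58.1% ± 0.728 (SD, n = 3) after re-aeration, against 68.4% ± 1.66 (SD, n = 3) in the dry seed. The region on chromosome 6 from 6665185 to 6665216 stood at 1.75% ± 3.03 (SD, n = 3, 19 to 40 reads) in 4 d nitrogen. It stood at 92.9% ± 5.28 (SD, n = 3, 214 to 277 reads) after re-aeration. The region on chromosome 11 from 8670062 to 8670078 stood at 91.0% ± 7.89 (SD, n = 3, 64 to 117 reads) after re-aeration. In 4 d nitrogen this chromosome 11 region had only 1 library with enough reads. In the octile of regions with the largest fall at 24 h, the mean level was 78.1% in the dry seed, 11.3% in 4 d nitrogen and 70.8% after re-aeration, and in that with the smallest fall it was 69.3%, 53.5% and 58.7%. These comparisons of the 4 d groups in the dry seed table were added after seeing the data.

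**Figure D4:**
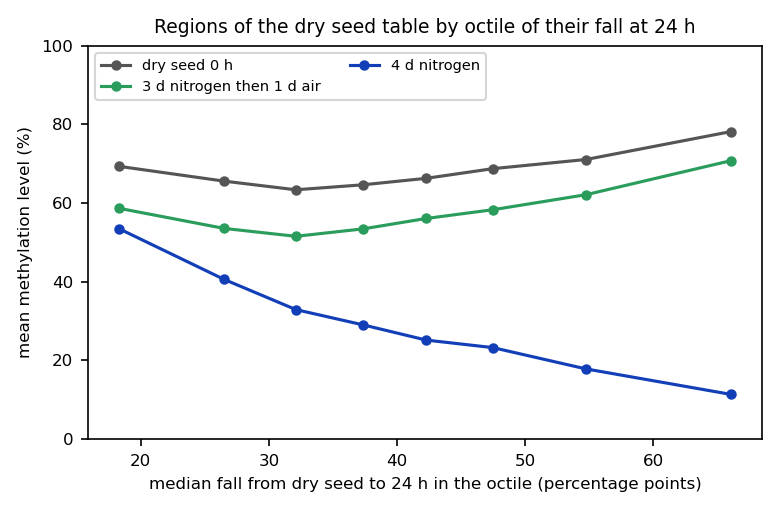
Mean methylation level in percent (y axis) of the dry seed, re-aeration and 4 d nitrogen groups in the regions of the dry seed table, by octile of their fall from the dry seed to 24 h (x axis, median of the octile in percentage points). From the smallest to the largest fall, nitrogen goes from 53.5% to 11.3% while re-aeration goes from 58.7% to 70.8%.

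Against 4 d nitrogen, the model called 4105 of 5873 tested regions higher after re-aeration and 20 lower. Of those higher, 3503 were not called against the dry seed, 590 were called below it and 12 above it. Against the dry seed, the model called re-aeration lower in 1504 of 5908 regions and higher in 13. The level itself was lower in 5059 regions and higher in 849, with a median difference of -9.47 points. The exact two-sided permutation p of the library means was 0.1 for both comparisons. With the spread taken from the dry seed and re-aeration libraries alone, 0 regions were called between them. Among the 1303 regions with a read ratio near that of the oxygen table, 489 were called higher than nitrogen and 9 lower.

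At 4 d the level was higher in nitrogen than in air in 4701 regions of the dry seed table and lower in 1114. The model called 112 of 5847 tested regions higher in nitrogen and 1 lower, with a median difference of 5.01 points. The exact two-sided permutation p of the library means was 0.1. The 1 region called lower, chosen after its values were seen, lay on chromosome 8 from 9212552 to 9212577. It stood at 31.4% ± 3.87 (SD, n = 3) in air and 5.55% ± 0.791 (SD, n = 2) in nitrogen. Its call was lost in 4 of the 6 fits with a library left out and could not be tested in the other 2, and it was also lost with the replicate block. The count of calls was 0 with the spread of the compared groups alone and 25 to 69 when any of the air or nitrogen libraries was left out.

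Within a gas, the quasi-binomial model called few regions between 24 h embryos and 4 d coleoptiles, with a median difference of -2.50 points in air and -0.24 in nitrogen. In air 2 regions were called lower and 0 higher at 4 d, with 643 regions at an unadjusted p under 0.05, while limma called 55 lower and 4 higher on the log2 ratio of methylated to unmethylated level, and 4 lower and 0 higher on the levels. In nitrogen 1 was called higher and 0 lower, with 220 regions at an unadjusted p under 0.05, and limma on the levels called 1 higher and 1 lower. Chosen after their values were seen, the regions in air were on chromosome 3 from 31261714 to 31261758, which went from 30.9% ± 9.47 (SD, n = 3) to 1.97% ± 2.00 (SD, n = 3), and on chromosome 7 from 8056030 to 8056102, which went from 51.9% ± 2.99 (SD, n = 3) to 33.9% ± 2.44 (SD, n = 3). The region in nitrogen, on chromosome 1 from 30467621 to 30467715, went from 57.4% ± 1.36 (SD, n = 3) to 82.7% ± 2.64 (SD, n = 3). The exact two-sided permutation p of the library means was 1 for 4 d against 24 h in nitrogen and 0.1, the smallest possible, for 4 d against 24 h in air. In air, the call on chromosome 7 was lost whichever library was left out, and that on chromosome 3 in all these fits but the one without 24 h air library 3, and the replicate block kept only that on chromosome 7. Leaving out 24 h nitrogen library 2 or 4 d nitrogen library 2 or 3 gave 0 in nitrogen.

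The last question was whether the tables held the same places. Regions of the re-aeration table lay mostly on regions of the dry seed table, whereas those of the oxygen table did not. Of the 902 re-aeration regions, 732 (81.2%) shared at least 1 bp with a dry seed region, against a mean of 1.68 and a highest value of 6 in 1000 random placements. The overlap held 720 of the 818 regions higher after re-aeration and 0 of the 61 lower, and Fisher's exact test, two-sided, gave p = 6.88e-51. In 4 d nitrogen the 61 stood at 67.3% and the dry seed regions at a mean of 29.3%, so the picking made their overlap unlikely. The test treats regions as independent, which they are not, and so does that of the oxygen overlap below. Of the 2131 oxygen regions, 19 (0.892%) overlapped a dry seed region, against a mean of 3.93 and a highest value of 12 in random placements. In 4 d nitrogen the oxygen regions stood at a mean of 70.1% and the 818 at 15.9%, so the picking made their overlap unlikely too. The re-aeration table overlapped the oxygen table in 10 regions, against a mean of 0.536 at random, and they held 8 of the 61 lower regions and 1 of the 818 higher, with p = 2.93e-09 in Fisher's exact test, two-sided. Of these 10 pairs, 9 were higher in nitrogen than in air and then lower after re-aeration, but 0 pairs were lower in nitrogen, and Fisher's exact test, two-sided, gave p = 1. Both changes share the nitrogen libraries. Over all oxygen regions the changes had opposite signs in 98.3%, against 64.4% in simulated unchanged groups, and the covariance was -56.5 against -19.5. The simulated groups were not picked for a difference between nitrogen and air, as these regions were, so part of the excess may come from the picking.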

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

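All tests in this part were chosen after the results were seen. The nitrogen minus air difference in the regions of the dry seed table was 3.16 points at 24 h and 6.10 points at 4 d, and limma's interaction term called 1 of 5897 regions (adjusted p = 0.0117), with 340 at an unadjusted p under 0.05. That region, on chromosome 1 from 40703352 to 40703367 with 3 sites, stood at 59.8% ± 10.2 in air and 37.1% ± 9.37 in nitrogen at 24 h, and at 29.6% ± 10.4 in air and 67.6% ± 6.02 in nitrogen at 4 d (SD, n = 3 each). Of 100 splits of the 12 libraries, the real one included, 17 gave as many regions and the highest other gave 63, so a chance arrangement of the libraries was not excluded. Of the others as large, 12 left the 3 libraries of each gas together at 4 d, the 63 among them, so they carry the gas difference at 4 d and follow that structure and not chance alone; splits that mixed the gases at 4 d gave at most 2. The split that exchanges air and nitrogen at 4 d, which adds the differences at both ages instead of subtracting them, was not among those drawn and gave 313.

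Total reads were tested in no comparison of methylation levels, and they differed between the groups too. Over the regions of the re-aeration table, the log2 ratio of reads in re-aeration over 4 d nitrogen exceeded that in the oxygen table by 0.77, with 0.69 to 0.93 over the pairs of libraries. In the dry seed table the dry seed over 24 h air had a median log2 read ratio of 0.82.

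The re-aeration libraries stood near the dry seed level in regions that were low at 24 h and at 4 d, and both groups also had more reads there and a wider spread between libraries. A constant share of dry-seed-like DNA in the re-aeration libraries could give a like regained share of the dry seed excess in every region. That holds only if both kinds of DNA yield reads alike and the rest stays at the 4 d nitrogen level. The regained share was 32.6% ± 1.57 (SD, n = 3) in the octile of regions with the smallest fall at 24 h. In the octile with the largest fall it was 88.9% ± 2.06 (SD, n = 3), a rise of 56.4 points. These conditions were not tested. The dry seed libraries had more reads in these regions, with a median log2 ratio of 0.82 over 24 h air, so the rise cannot decide. Better recovery of methylated reads in every library would raise the log2 read ratio of 4 d nitrogen over 4 d air in the oxygen table above that in the re-aeration table by 0.34, and the observed change was -0.023, with -0.13 to 0.13 over the pairs of libraries. Methylated reads added to an unchanged set would leave the unmethylated reads as they were, but in the 818 higher regions these stood at 55.5% of nitrogen as deposited (49.4% to 61.5% over the pairs), and at 66.4% (62.4% to 73.6%) when scaled by the reads of the same libraries in the oxygen table. The read ratios argue against better recovery in every library as the whole cause. The unmethylated reads argue against added methylated reads as the whole cause only if reads in the oxygen table follow the depth of the libraries. That depth is not known here, and re-aeration differed from nitrogen in that table too. A constant share of dry-seed-like DNA, a gain of methylation after the switch to air and a different mix of cells stay open. So does a library preparation shared by the dry seed and re-aeration groups, which the labels do not record. Such a preparation would bear on the fall from the dry seed to 24 h too. All of these may act together.

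In the oxygen table the re-aeration level lay between those of 4 d nitrogen and 4 d air. Picking regions by chance high values in the nitrogen libraries would also place re-aeration below nitrogen; a simulation with picking alone gave a median of -0.82 points, against -14.8 observed, but the nitrogen libraries from which the fall is measured took part in the picking, and a simulation rests on an assumed spread, so this stays open. A difference in read depth stays open too. In 1190 regions whose read ratios lay near the medians of the oxygen table, the return was 50.3%. Their levels were 38.7% ± 1.84 in air, 54.2% ± 0.364 after re-aeration and 70.0% ± 0.409 in nitrogen (SD, n = 3). Those medians on the log2 scale were 0.15 for nitrogen over air and -0.26 for re-aeration over nitrogen. The groups thus still differed in depth in these regions, so this test cannot decide. A partial return of methylation within 1 d of air, and a mix of cells formed before and after the switch, may also be considered as hypotheses and stay open and untested.

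Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. A mixed split also moves the difference between the real groups into the spread within groups, which lowers its count. Where regions were picked for a difference between the groups compared, low counts in the other splits were set in advance and are not evidence. The real split gave 5845 regions from the dry seed to air, 5707 to nitrogen, 1 for 24 h nitrogen against air, 2103 for 4 d nitrogen against air and 879 for re-aeration against nitrogen, and the highest other split gave 1, 2, 0, 0 and 0. In the dry seed table the real and highest other counts were 113 and 0 for 4 d nitrogen against air, 4125 and 1 for re-aeration against nitrogen, 1517 and 69 for re-aeration against the dry seed, 2 and 0 for 4 d against 24 h in air, and 1 and 0 in nitrogen. They were 835 and 0 for re-aeration against nitrogen and 873 and 0 against air in the oxygen table, and 2 and 0 for nitrogen against air in the re-aeration table.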

How the results depend on the processing

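Values for limma on the levels, for the spread without the dry seed and re-aeration libraries and for regions of like read ratio come from alternatives chosen after seeing the data. No alternative run gave more calls against the reported direction of a comparison than along it. For 4 d nitrogen against air the count stayed between 1903 and 2117 over 17 alternatives, around 2103. From the dry seed to air and to nitrogen it stayed within 1.5 times of 5845 and 5707 except in regions with at least 8 sites, where fewer regions could be called (2679 and 2676). In those regions the other counts were 0 for 24 h nitrogen against air, 4 for 4 d nitrogen against air, 2401 for re-aeration against nitrogen, 423 for re-aeration against the dry seed, 0 for 4 d against 24 h in air and 0 in nitrogen.

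With the spread of the compared groups alone, which leaves fewer libraries to estimate it, the count was 0 for 24 h nitrogen against air, 0 in the dry seed table for 4 d nitrogen against air, for re-aeration against the dry seed, and for 4 d against 24 h in either gas, 420 for re-aeration against nitrogen and 378 against air in the oxygen table, and 0 for nitrogen against air in the re-aeration table. Without the dry seed and re-aeration libraries in the spread it was 0 for 24 h nitrogen against air, 0 for 4 d against 24 h in air and 0 for nitrogen against air in the re-aeration table. Limma on the arcsine square root, on the log2 ratio and on the level called 2, 2 and 5 regions for 24 h nitrogen against air, 222, 275 and 239 for 4 d nitrogen against air in the dry seed table, 9, 59 and 4 for 4 d against 24 h in air, 2, 2 and 2 in nitrogen, and 10, 14 and 12 for nitrogen against air in the re-aeration table. On the log2 ratio it called 760 for re-aeration against the dry seed. The cause of these differences between tests was not tested.

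A minimum of 20 points, by its construction, lowered the count to 50 for 4 d nitrogen against air and 772 for re-aeration against the dry seed in the dry seed table, 1 for 4 d against 24 h in air, and 404 and 505 for re-aeration against nitrogen and against air in the oxygen table. Regions of like read ratio, which are fewer, gave 106 calls for re-aeration against nitrogen in the re-aeration table and 498 in the dry seed table. The replicate block gave 4 for 4 d against 24 h in air, 329 and 462 for re-aeration against nitrogen and against air in the oxygen table and 0 for nitrogen against air in the re-aeration table, and moved no other count by over 1.5 times. The libraries share only a number: correlations of same-numbered libraries lay between -0.050 and 0.051, and at most 4 of 6 libraries were closest to their own number.

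With each library left out in turn, the count was 0 to 1 for 24 h nitrogen against air, 25 to 69 for 4 d nitrogen against air in the dry seed table, 0 to 2 for 4 d against 24 h in air, 0 to 1 in nitrogen, 197 to 324 for re-aeration against nitrogen and 373 to 647 against air in the oxygen table, and 0 to 0 for nitrogen against air in the re-aeration table. Against nitrogen in the oxygen table it was 324, 247 and 276 without nitrogen library 1, 2 and 3 and 271, 197 and 261 without re-aeration library 1, 2 and 3. Against air it was 419 and 417 without air library 2 and 3 and 450, 422 and 373 without re-aeration library 1, 2 and 3. In the dry seed table, 4 d nitrogen against air had 69, 33 and 25 calls without air library 1, 2 and 3 and 58, 42 and 52 without nitrogen library 1, 2 and 3. Fewer libraries were left in each of these fits.

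The difference in mean level kept its sign in each comparison except 4 d against 24 h in nitrogen, where it was 0.0848 points and turned to -0.283 as a median, to -0.294 weighted by length and to between -0.308 and 0.315 with a library left out. With at least 50% of each region shared, 385 re-aeration regions lay on dry seed regions, 5 oxygen regions on dry seed regions and 6 re-aeration regions on oxygen regions. The highest values in random placements were 4, 6 and 2, so the 5 oxygen regions did not exceed theirs. Of 383 alternatives for the regions named for their size of difference, which counted per comparison are 28, 376 kept the call, and the 7 that lost it were all of the chromosome 8 region at 24 h. Most of the others, named because few were called in their direction, held less well. Without 1 library at a time, the calls were lost in 3 of 6 fits for chromosome 9 from the dry seed to air, 4 of 6 for chromosome 8 in the dry seed table at 4 d, where 2 could not be tested, 5 and 6 of 6 for chromosomes 3 and 7 for 4 d against 24 h in air, 3 of 6 for chromosome 1 in nitrogen, 5 of 6 for chromosome 11 for re-aeration against air in the oxygen table, and 6 of 6 for both regions for nitrogen against air in the re-aeration table. The position of regions relative to genes and the gene lists, with their alternatives, were not run.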

Other observations

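The tests of the chromosome starts and those named in the last paragraph were chosen after the results were seen. Regions of all 3 tables lay on all 12 numbered chromosomes. The dry seed table had between 9.71 and 18.4 regions per Mb of the span covered by regions, with the lowest density on chromosome 12 and the highest on chromosome 11. The oxygen table had between 3.89 and 7.99 regions per Mb, lowest on chromosome 12 and highest on chromosome 3. The re-aeration table had between 1.64 and 2.98 regions per Mb, lowest on chromosome 12 and highest on chromosome 1.

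The first 5000 bp of the chromosomes held more regions than an even spread gives in the dry seed and re-aeration tables. There were 8 dry seed regions against 0.951 expected (exact binomial p = 7.13e-06) and 6 re-aeration regions against 0.145 expected (exact binomial p = 1.12e-08), each on 6 of the chromosomes. The oxygen table had 0 regions there, against 0.343 expected (exact binomial p = 1). The even spread ignores where regions are callable. Because 732 of the 902 re-aeration regions overlap dry seed regions, these tables do not give separate evidence.

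In the authors' deposited table, all 3 dry seed libraries and no other were listed as high in 4053 of 5908 regions, and 2 dry seed libraries and no other in 1697. A 24 h library was listed as high in 158 regions. All 6 of the 24 h libraries were listed as low in 1575 regions. An air library but no nitrogen library was listed as low in 374 regions, and a nitrogen library but no air library in 106.

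A hypothesis was that all regions of the oxygen table returned by a single share after re-aeration. In that case the return shares computed from separate sets of libraries would not correlate across regions. Spearman's rho, across regions and not across independent replicates, averaged 0.143 over the 3 pairs of sets, with 0.117 to 0.165 between pairs. The interquartile range of the share was 26.9 points, against 20.7 points in 100 simulations with a single share. The regions may thus differ in how far they returned, although the correlation is low and a region's own measurement bias could also raise it.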
